A study of Homo sapiens with 6 samples.

How the data were processed

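RNA of HUVEC under the NCC and ACC waveforms was measured on 6 arrays with a single label each. Per the labels' protocols, the cells were held in medium with 2% serum and 2.8% dextran, the waveforms were applied for 24 h, and 40 µg of total RNA was extracted and turned into digoxigenin-labelled cDNA by the ABI protocol. The deposited table held, per the values themselves, the authors' intensity for each probe and array, a linear signal above 0 with blanks and no zeros. Scanner, software, background correction, scaling between arrays and the rule behind the blanks are not given in the sources used here, so the scale of the signal is not known beyond being linear. Blanks made up 35.4% to 51.0% of the probes of an array, and 3390 probes were blank on all arrays.

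Groups followed the sample titles and source names. The array titled NCC 3 carries a treatment text worded as ACC, and it was kept in NCC. Nothing in the labels says whether the replicates were separate cultures or donors, so p-values measure only the spread between these samples, which may be technical. The groups, the tests, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, apart from the added alternatives named here.

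Analysis used R 4.3.3 and limma 3.58.1. Probes with a signal on all 6 arrays (10323) were quantile normalized between arrays, floored at the 10th percentile of the positive values (a signal of 2.98) and log2 transformed. The dimmest 40% by mean over all arrays were left out, which left 6194 probes. A fold for a gene with signals at the floor understates its difference. Gene names came from the platform annotation, which listed 17212 of the probes, 17073 with 1 symbol and 139 with several. Current symbols were looked up by gene identifier for 17063, and 15666 probes of the table were unnamed here. Of the filtered probes, 3878 had 1 symbol, and each gene was represented by its brightest probe, giving 3628 genes. No called gene had probes that disagreed in direction, and 4 had several. Coordinates are not given because no genome build is named for the array.

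The ACC and NCC arrays were compared with lmFit and eBayes in limma, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Lists were tested with camera at an inter-gene correlation of 0.01, adjusted over the 25 lists with at least 3 tested members, of 31 written (25 pathway lists and 6 cell type marker lists). They covered shear and KLF2 responses, NRF2, NF-kB, vessel identity, angiogenesis, YAP and TEAD, BMP, matrix, paracrine factors, cell cycle, metabolism, stress, interferon, vasomotor, junction, haemostasis, cytoskeleton, ribosome and mitochondrial genes, and markers of endothelial, mural, fibroblast, leukocyte, erythroid and epithelial cells. Lists share members, such as CCL2 and CXCL8 in the shear-repressed and NF-kB lists.

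The named genes were the 12 with the largest differences in each direction among those that passed and separated all arrays, up to 4 passing members of each list (or the 2 with the smallest p where none passed), and 8 genes fixed by name, KLF2, KLF4, NOS3, THBD, EDN1, CCL2, VCAM1 and GJA5. Other list members are named as examples chosen after their values were seen. Genes under the dim filter were taken from a fit without filter or floor, which covered 6344 genes.

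Replicate numbers are shared between the groups. Deviations from the group means correlated across genes at 0.53, 0.17 and 0.44 between the arrays numbered 1, 2 and 3, all over 0.1, so by a rule on same-numbered arrays alone the numbers were taken to pair the samples. Of the other pairs, ACC 3 with NCC 2 reached 0.172, slightly above the 0.166 of the arrays numbered 2, so the data single out that pair less clearly. This pairing comes from the data, since the labels give only the numbers. The design kept the block out of the main comparison, and blocked values are given where they change a call.

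The fit was tested on simulated data for ACC against NCC, with 200 of 3628 genes changed. It recovered 67% of the genes changed 2-fold and 99% of those changed 4-fold, with 10 false calls among 176. The simulated values were drawn independently across genes and arrays, without pairing, correlation between genes or a floor. These rates may therefore not hold for the real arrays.

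Alternatives covered the signals as deposited, median centring, a floor at the 25th percentile, a pseudocount, no dim filter, leaving out the dimmest 50%, probes with at least 2 values per group, the replicate block, an intensity trend, robust variance, array weights, other thresholds, the mean of a gene's probes, moving NCC 3, leaving out each array or pair, an estimated inter-gene correlation and fry. With at least 2 values per group and with robust variance, lists were tested by camera's preranked form, on z-scores of the gene statistics. Fits without filter and floor, with and without the block, and a fit that kept unnamed probes were added after seeing the data. Left out were probes blank on any array and, for gene names, probes with several symbols or none.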

Results

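Gene expression was measured in human umbilical vein endothelial cells (HUVEC), primary cells from the inner lining of the umbilical vein, kept for 24 h under computed waveforms of shear stress, the drag of flowing fluid on the cell surface. The waveforms stood for flow in coronary collaterals, the vessels that bridge coronary branches. One waveform represented normal collaterals (NCC) and the other collaterals undergoing adaptive remodeling (ACC), and the series asked which endothelial genes respond differently to them. Each group held 3 arrays, numbered 1 to 3, with 1 sample per array. The table listed 32878 probes, of which each array gave a signal for 16116 (NCC 1) to 21228 (NCC 2) and left the others blank. Median signal per array lay between 3.365 (NCC 2) and 5.74 (NCC 3). Over the 10323 probes listed on all 6 arrays, the median signal was 9.74 in NCC 1 and 11.22 in ACC 1, against 13.47 to 15.85 in the other 4 arrays. The number of arrays limits the precision of every comparison. Differences are given as ACC minus NCC on the log2 scale of normalized signal, each ± its standard error (SE) with 3 arrays per group. The SE and the adjusted p-values are from limma, which draws each gene's variance toward a value shared by all genes. For genes with a wide spread between arrays, such as CYP1B1, the SE is therefore smaller than their own arrays alone would give.

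Under the ACC waveform, endothelial genes known to respond to shear stress differed from their levels under the NCC waveform. KLF2, a transcription factor induced by steady laminar flow, was 5.43-fold higher (2.44 ± 0.31 SE, adjusted p = 0.0039), with a mean normalized signal of 394 ± 116 (SD, n = 3) in ACC and 72.8 ± 22.1 (SD, n = 3) in NCC. Thrombomodulin (THBD), an anticoagulant receptor for thrombin, was 3.91-fold higher (1.97 ± 0.39 SE, adjusted p = 0.0234). PLAT, the tissue plasminogen activator that starts fibrin breakdown, was 11.3-fold higher (3.50 ± 0.29 SE, adjusted p = 0.000345). Endothelin-1 (EDN1), a vasoconstrictor peptide, was 3.49-fold lower (-1.80 ± 0.31 SE, adjusted p = 0.0149), and the monocyte chemokine CCL2 was 5.38-fold lower (-2.43 ± 0.28 SE, adjusted p = 0.00194).

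Of 3628 genes tested, 120 passed an adjusted p of 0.05, 66 higher and 54 lower in ACC. In each of the 120, all 3 ACC arrays lay on one side of all 3 NCC arrays. Passing the threshold with 3 arrays per group nearly ensures this, so it adds no separate support. Such separation held for 739 of all genes tested (20.4%), where 10% is the share that chance gives if the arrays are exchangeable, which paired arrays are not. The median fold among the 120 was 2.71, and 115 differed by over 2-fold and 18 by over 4-fold. With the replicate number as a block, 290 genes passed, 150 higher and 140 lower, and they included all 120. The count was 56 without ACC 1, 30 without ACC 3, 60 without NCC 2, 37 without NCC 3, and 0 when NCC 3, whose treatment text is worded as ACC, was moved to ACC (209 at an unadjusted p of 0.05). It was 60 on the signals as deposited, with 70% of calls higher in ACC in place of 55%, and 6 or 32 when dim probes were kept, with or without the floor on low signals.

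**Figure D1:**
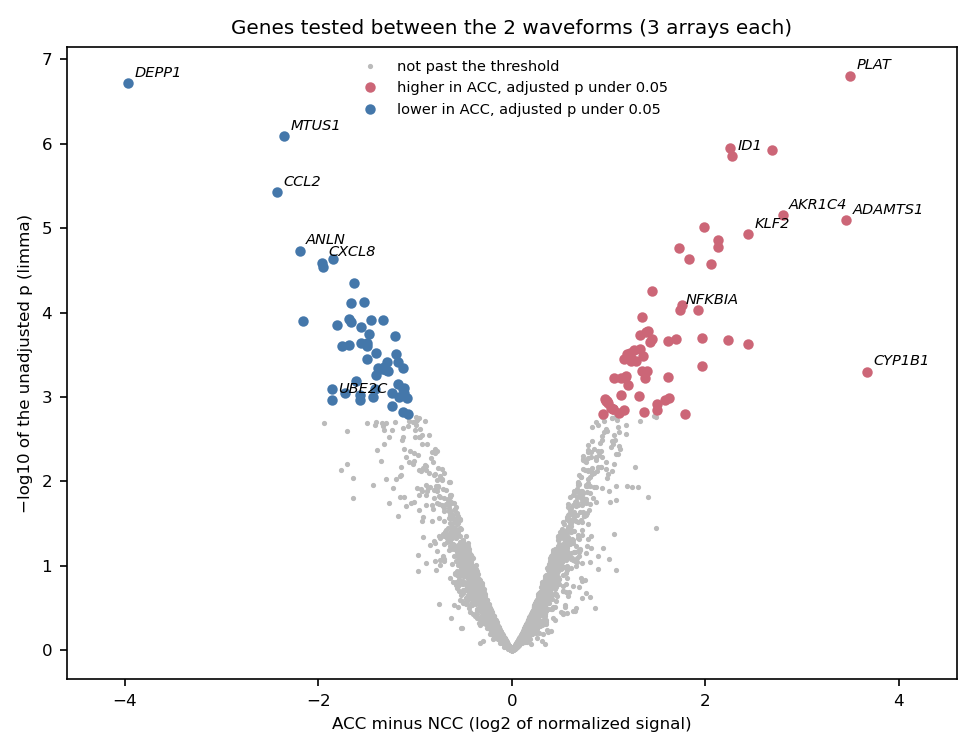
Each point is 1 of the genes tested, with the log2 difference in normalized signal (ACC minus NCC, 3 arrays each) on the horizontal axis and −log10 of the unadjusted limma p on the vertical axis. The 66 genes past the adjusted threshold and higher in ACC lie to the right and the 54 lower to the left, with PLAT and DEPP1 highest on the vertical axis.

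The 12 genes with the largest rises were led by CYP1B1, a cytochrome P450, which was 12.8-fold higher (3.68 ± 0.74 SE, adjusted p = 0.0239), with a wide spread between arrays (mean normalized signal 204 ± 156 in ACC, SD, n = 3). The aldo-keto reductases AKR1C4 and AKR1C1 were higher by 2.80 ± 0.34 and 2.44 ± 0.45 (adjusted p = 0.00316 and 0.0173). Both belong to a family of close paralogs and the probe sequences were not examined, so which member gave the signal is uncertain. AKR1C1 lay at the floor on NCC 3, and it was 5.94-fold higher without filter or floor. The secreted metalloprotease ADAMTS1 was higher by 3.46 ± 0.43 on the log2 scale (adjusted p = 0.00321), and the membrane protease ADAM19 was 4.39-fold higher. PLPP1, a lipid phosphate phosphatase, rose 6.44-fold and ID1, an inhibitor of helix-loop-helix transcription factors, rose 4.83-fold (both adjusted p = 0.000844). MRPS6, a mitochondrial ribosomal protein, rose 4.77-fold, the MAP kinase phosphatase DUSP5 rose 4.69-fold and NDRG1, a stress-responsive gene, rose 4.37-fold.

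The largest fall was in DEPP1, a target of FOXO transcription factors, at 15.6-fold (-3.96 ± 0.33 SE, adjusted p = 0.000345). Its signal lay at the floor of 2.98 on 2 of the 3 ACC arrays, and in the fit without filter or floor it was 20.2-fold lower. MTUS1, which encodes a microtubule-associated protein, was 5.11-fold lower and the cytokinesis protein ANLN 4.56-fold lower. CXCL8, a neutrophil chemokine, fell by 1.96 on the log2 scale (adjusted p = 0.00511), and the chemokine CCL14 fell by 1.75. Thrombospondin-1 (THBS1), an anti-angiogenic matrix glycoprotein, was 3.87-fold lower, from a mean normalized signal of 877 ± 70.7 in NCC to 237 ± 91.7 in ACC (SD, n = 3). RRM2, a subunit of ribonucleotide reductase, was 4.47-fold lower and UBE2C, a ubiquitin-conjugating enzyme of mitotic exit, 3.63-fold lower. Both lay at the floor on ACC 3, and without filter or floor the log2 differences were -2.38 for RRM2 and -1.99 for UBE2C. Keratin 7 (KRT7) and the beta-tubulin TUBB3 were 3.62-fold and 3.59-fold lower.

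**Figure D2:**
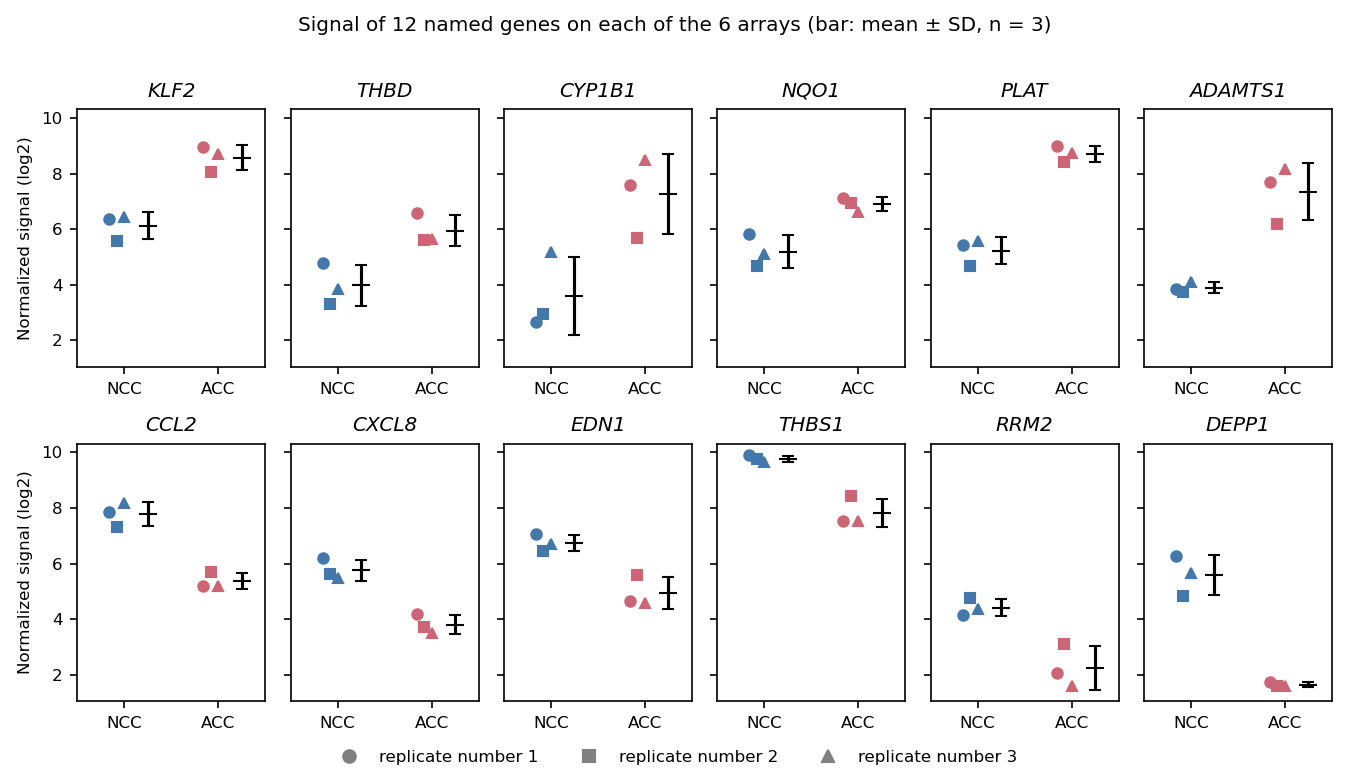
Log2 normalized signal of 12 genes on each array, grouped by waveform, with marker shapes for the replicate number and bars for the mean ± SD (n = 3). For each gene shown, all 3 ACC arrays lie on one side of all 3 NCC arrays, and CYP1B1 has the widest spread within groups.

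Genes that shear stress and KLF2 induce were higher as a list. Of 8 tested members of that list, 5 rose and none fell (7 rose when adjusted over the list alone), namely CYP1B1, KLF2, THBD, NQO1 and the angiopoietin receptor TEK, which was 2.84-fold higher. The list median was 1.60 and the camera test gave an adjusted p of 5.76e-08, which became an adjusted p = 0.110 with an estimated correlation. Among the 8 tested genes that shear stress or KLF2 represses, 7 fell (7 when adjusted over the list alone), among them EDN1, CCL2, CXCL8 and BMP4, a bone morphogenetic protein that was 2.95-fold lower. That list had a median of -1.56 and an adjusted p of 1.19e-11 (adjusted p = 0.110 with an estimated correlation). Endothelial nitric oxide synthase (NOS3) and the adhesion molecule VCAM1 were too dim for the filter. In the fit without filter or floor NOS3 differed by 1.70 ± 0.52 (adjusted p = 0.185, or 0.0316 with the replicate block) and VCAM1 by -1.70 ± 0.49 (adjusted p = 0.163, or 0.0209 with the block). KLF4 and the arterial connexin gene GJA5 were not tested, because blanks left KLF4 with a signal on 1 ACC and 2 NCC arrays and GJA5 on 3 ACC and 1 NCC arrays, at 1.53 or less.

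Antioxidant targets of NRF2, the transcription factor of the oxidative stress response, were higher as a list, with each of the 9 tested above 0. Of these, 3 rose (7 when adjusted over the list alone), which were AKR1C1, malic enzyme ME1 (3.97-fold, adjusted p = 0.00349) and the quinone reductase NQO1 (3.25-fold, adjusted p = 0.0173). HMOX1, heme oxygenase, differed by 1.49 ± 0.36 (adjusted p = 0.05005, or 0.00579 with the replicate block) and did not pass without the block. The list's adjusted p was 8.06e-08 (adjusted p = 0.110 with an estimated correlation), and it shared HMOX1 and NQO1 with the shear-induced list. In the fit without filter or floor, 10 of 11 NRF2 targets tested were above 0, with a median of 0.84. GCLC (0.13) and SRXN1 (-0.02), too dim for the filter, were near 0 there. Of 4 tested members of the NF-kB inflammatory list, CCL2 and CXCL8 fell, while NFKBIA, which encodes the NF-kB inhibitor I-kappa-B-alpha, rose 3.33-fold (adjusted p = 0.0125). Adjusted over the list alone, 1 rose and 3 fell, the latter including CXCL1 (-1.76 ± 0.53, adjusted p = 0.109 over all genes, or 0.00522 with the block). The list was lower at an adjusted p of 0.0163 (adjusted p = 0.160 with an estimated correlation), but at 0.0556 without ACC 2, 0.0893 with the dimmest 50% left out and 0.339 with NCC 3 moved. Its median was -1.86 over the 4 tested. Without filter or floor it was -0.57 over 10 members, of which 8 were below 0 and 2 above.

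Matrix-degrading proteases and their inhibitors were higher as a list, and structural matrix genes lower. PLAT, ADAMTS1, cathepsin L (CTSL, 2.35-fold), ADAM15 (2.34-fold) and the protease inhibitor SERPINE2 (2.28-fold) rose among 11 tested, none fell, and 6 rose when adjusted over the list alone. That list's adjusted p was 1.54e-05 (adjusted p = 0.110 with an estimated correlation). Its median was 1.19, or 0.64 over 15 members without filter or floor, of which 10 were above 0 and 5 below. MMP1 (-0.04), MMP2 (-0.36) and PLAU (-0.58) did not pass. Of 18 structural matrix genes, the cross-linking enzyme LOX (2.75-fold) and the basement membrane collagen COL4A1 (2.18-fold) fell and fibrillin-1 (FBN1) rose 2.39-fold. The other 15 did not pass, and adjusted over the list alone 1 rose and 4 fell. The median was -0.33 and the adjusted p 0.00274 (adjusted p = 0.110 with an estimated correlation).

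Cell cycle genes were lower under ACC. Each of the 10 tested had a difference below 0, with a median of -1.17, and RRM2, UBE2C and the replication helicase subunit MCM2 (2.46-fold) fell, or 9 members when adjusted over the list alone. TOP2A (-1.71 ± 0.50, adjusted p = 0.0999, or 0.00514 with the block) and PCNA (-0.80 ± 0.22, adjusted p = 0.0843, or 0.037 with the block) did not pass over all genes without it. The list's adjusted p was 3.43e-09 (adjusted p = 0.160 with an estimated correlation). Targets of the mechanosensitive YAP and TEAD factors were lower too, with THBS1 and the matricellular genes CCN2 (2.95-fold) and CCN1 (2.66-fold) falling among 10 tested. Adjusted over the list alone, 5 fell and 1, ANKRD1 (1.30 ± 0.43, adjusted p = 0.143 over all genes), rose. This list's adjusted p was 4.19e-05 (adjusted p = 0.198 with an estimated correlation). In the contractile cytoskeleton list, the actin-binding protein gene CALD1 (2.89-fold) fell and the other 6 tested did not pass, with 3 falling when adjusted over the list alone. It was lower at an adjusted p of 0.0163 (adjusted p = 0.160 with an estimated correlation) but at 0.0526 without NCC 2 and 0.0712 with NCC 3 moved.

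The arterial and Notch list was higher at an adjusted p of 0.0356 (adjusted p = 0.188 with an estimated correlation). Of its 4 tested members, the Notch ligand JAG1 rose 2.51-fold (1 also when adjusted over the list alone), and JAG2, SOX17 and SOX7 were at 0.60, 0.10 and 0.27 without passing. With probes of at least 2 values per group, the list's adjusted p was 0.832 over 9 members by camera's preranked form. By camera it was 0.116 with array weights, 0.0648 without ACC 1, 0.19 without NCC 1 and 0.0542 with NCC 3 moved. In all, 10 of the 25 lists tested passed with camera's preset correlation, and 0 passed with an estimated one (7 at an unadjusted p of 0.05). Fry's directional test, which asks only whether a list's genes move one way, passed 10. Its mixed test, which asks whether members differ in either direction, also passed lists without a common direction. Among these were BMP and SMAD signalling (adjusted p = 0.000235) and angiogenic tip cell (adjusted p = 0.000387). It did not pass ribosomal proteins (adjusted p = 0.796) or mitochondrial respiration (adjusted p = 0.886).

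**Figure D3:**
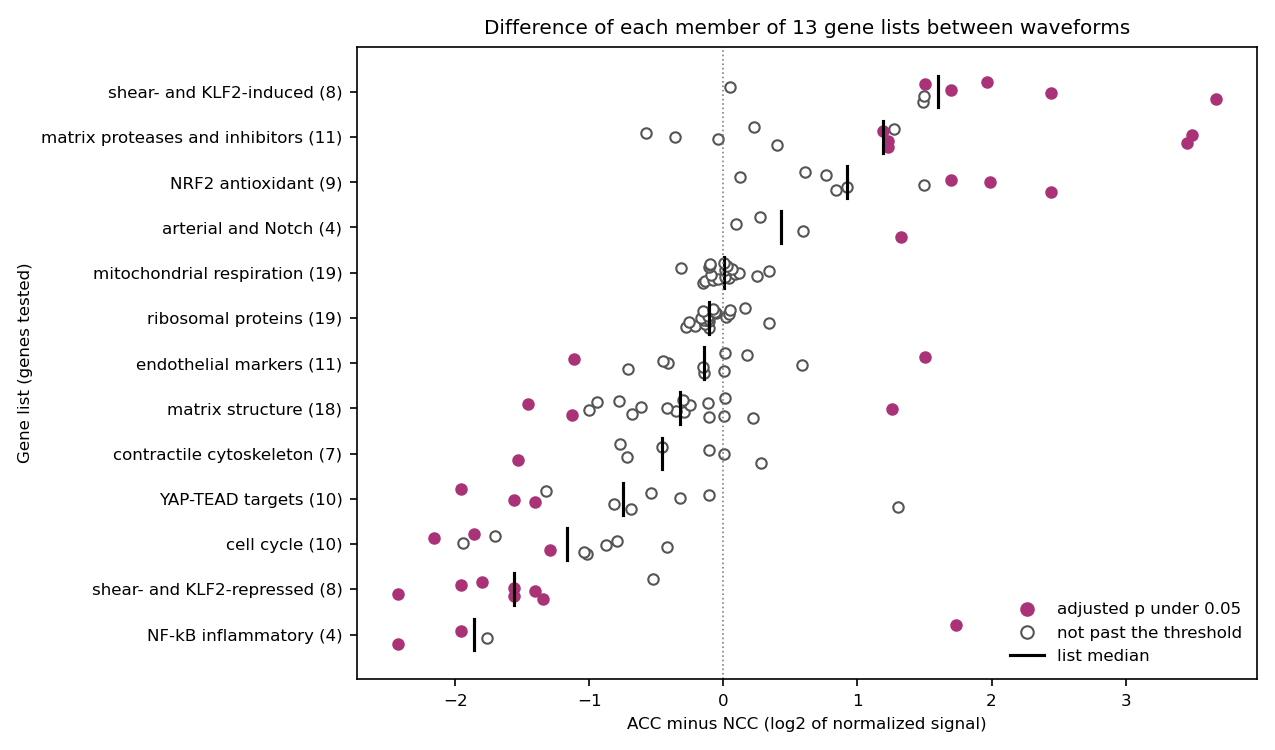
Log2 difference in normalized signal (ACC minus NCC, 3 arrays each) for the tested members of 13 gene lists, with the number tested beside each name, filled points for genes past the adjusted threshold and a black line at each list's median. The 10 lists past the camera threshold stand beside mitochondrial respiration, ribosomal proteins and endothelial markers, whose medians were 0.002, -0.11 and -0.14.

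Several lists that did not pass held genes that moved in opposite directions. Among 10 BMP and SMAD genes, ID1 rose while BMP4 and BMP2 (2.79-fold) fell, and adjusted over the list alone 3 rose and 2 fell. Its median was -0.17, its mean 0.05 and its test pointed lower, at an adjusted p of 0.913. Without filter or floor its median was 0.37 over 13 members and camera pointed higher (adjusted p = 0.523). Of 7 paracrine factors, VEGFC (3.07-fold), a lymphangiogenic growth factor, and FGF2 (2.48-fold) rose and BMP2 and EDN1 fell (adjusted p = 0.465 for the list, and 2 up and 3 down when adjusted over the list alone). Among 9 genes on the angiogenic tip cell list, VEGFC and TEK, the latter also on the shear-induced and endothelial marker lists, rose and ESM1 (-1.32) fell (list adjusted p = 0.487, with 2 up and 3 down when adjusted over the list alone). With at least 2 values per group that list was lower over 11 members (adjusted p = 0.0399 by camera's preranked form, against an adjusted p = 0.751 with an estimated correlation over the 9). Among 8 vasomotor genes, RAMP2 (2.58-fold), part of the adrenomedullin receptor, rose while EDN1 and adrenomedullin itself (ADM, 2.54-fold) fell, as they did when adjusted over the list alone. The vasomotor median was 0.14, but its mean was -0.07 and its test pointed lower (adjusted p = 0.721). Without filter or floor that list's median was 0.24 over 13 members and camera pointed higher (adjusted p = 0.418). In haemostasis, PLAT and THBD rose among 13 tested, and 3 rose and 3 fell when adjusted over the list alone. The median there was -0.53 and the mean 0.06, and the test pointed lower (adjusted p = 0.824).

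Among the remaining lists, DUSP5 rose and DUSP6 (3.22-fold), another MAP kinase phosphatase, fell among 7 immediate early genes (list adjusted p = 0.652, with 1 up and 2 down when adjusted over the list alone). NDRG1 rose and ADM fell among 9 hypoxia and glycolysis genes (adjusted p = 0.731, with 2 up and 1 down when adjusted over the list alone). In the unfolded protein response, TRIB3 rose 2.25-fold and the other 14 did not pass (adjusted p = 0.75, with 1 up when adjusted over the list alone). No member passed over all genes in heat shock, sterol and fatty acid synthesis, junctions, interferon, ribosomal proteins or mitochondrial respiration, whose adjusted p-values were 0.407, 0.188, 0.593, 0.75, 0.59 and 0.856. Adjusted over the list alone, 1 heat shock gene rose and none did in the other 5 lists. HSPH1, a heat shock protein, differed by 1.06 (adjusted p = 0.0614, or 0.0152 with the replicate block) and the desaturase SCD by 0.93 (0.145, or 0.0191 with the block). The mitochondrial list had a median of 0.002 and a mean of -0.008, and its test pointed lower.

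Endothelial identity markers did not move one way as a list past the threshold, though fry's mixed test passed them (adjusted p = 0.00159). Of 11 tested, TEK rose and ROBO4, a guidance receptor, was 2.16-fold lower, as when adjusted over the list alone, and the list gave an adjusted p of 0.631. Von Willebrand factor (VWF) and VE-cadherin (CDH5) differed by 0.01 ± 0.22 and 0.01 ± 0.22. Markers of other cell types were rarely measurable. The leukocyte list had 1 tested gene, CD68 (1.33 ± 0.32, adjusted p = 0.0514, or 0.0114 with the replicate block), which macrophages express strongly and other cells also hold in lysosomes. CD68 was higher past the threshold in 13 of 26 alternatives. These include an adjusted p of 0.1 and an unadjusted p of 0.05 with 1.5-fold, looser thresholds that its values in the main fit already met. The pericyte marker RGS5 differed by -0.19, the fibroblast collagens COL1A2 and COL3A1 by -0.11 and 0.01, and the venous and lymphatic list was represented by EMCN alone (0.59), none of which passed. In the fit without filter or floor, the mural marker TAGLN differed by -0.97 ± 0.32 (adjusted p = 0.218) and the fibroblast marker DCN by -0.88 ± 0.29 (adjusted p = 0.218). Each was lower when adjusted over its list alone, but these lists had only 2 and 3 tested genes there, so that adjustment is slight. No member of the erythroid and epithelial lists could be tested, and KRT7, which simple epithelia express and which was not on the list, was 3.62-fold lower (adjusted p = 0.0326).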

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

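Gene counts moved with the settings far more than list counts at camera's preset correlation. This does not make the list calls the more secure, since other splits of the arrays passed up to 5 lists but 0 genes. Against 120 genes (55% higher in ACC), the signals as deposited gave 60 (70% higher), no dim filter 6, the replicate block 290, array weights 345, an adjusted p of 0.1 224, an unadjusted p of 0.05 with 1.5-fold 481, and moving NCC 3 to ACC 0 (209 at an unadjusted p of 0.05 in limma). With no dim filter, 116 genes lay at the floor on all arrays and had no variance. Without filter and floor, a setting chosen after seeing the data, the count was 32 (65.6% higher), and 202 with the replicate block. Leaving out arrays gave 13 to 137 genes. The count was 56 without ACC 1, 30 without ACC 3, 60 without NCC 2 and 37 without NCC 3, and of the pairs 52 without number 2 and 13 without number 3. The other settings gave 119 to 163. The cause of the shifts was not tested. All 49 named genes that passed kept their direction in every alternative that tested them. Their arrays were fully separated by group when they were chosen, so this was close to certain beforehand and adds no separate support. All 49 lost the threshold when NCC 3 was moved, 45 with no dim filter, 36 without pair 3, 32 without filter and floor, 24 without pair 2, 15 on the signals as deposited and 8 without pair 1. Of single arrays left out, 26 lost it without ACC 3, 25 without NCC 3, 17 without ACC 1, 15 without NCC 2, 10 without ACC 2 and 6 without NCC 1. Lists past the threshold numbered 8 to 11 in every setting except the estimated correlation, which left 0 (7 at an unadjusted p of 0.05). Besides, the arterial and Notch list lost the threshold in 6 settings (adjusted p up to 0.832) and the NF-kB and contractile lists in 3 each (up to 0.339 for NF-kB). Calls were gained by the angiogenic tip cell list with at least 2 values per group (lower, 0.0399), by sterol and fatty acid synthesis with NCC 3 moved (higher, 0.0434) and by interferon with dim probes kept. The unadjusted rule gave no list value. The block changed no list call, and among the genes named it added calls for CD68, HSPH1, SCD, HMOX1, CXCL1, TOP2A and PCNA. In the fit without filter and floor it added them for NOS3, VCAM1, TIMP3, FGF18, IFIT3 and IFI44, which the main fit did not cover. It also restored others there, since 32 of the named genes that passed lost the threshold without the block and 4 with it. The 10323 of 32878 probes with a signal on all arrays limit which genes could be compared.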

Other observations

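The tubulin family, the probes listed in a single group and the genes named in this paragraph and the next were chosen after their values were seen, while the tests in the later paragraphs were written down before their results, except that of a shared array factor, chosen after. In the fit without dim filter and floor, the interferon list had 10 tested members, 8 above 0, and was higher in ACC (adjusted p = 0.0217, and adjusted p = 0.210 with an estimated correlation). IFIT2, an interferon-induced antiviral gene, was 4.58-fold higher (2.20 ± 0.36 SE, adjusted p = 0.039), while IFIT3 (1.62 ± 0.33, adjusted p = 0.0693, or 0.0316 with the replicate block) and IFI44 (-1.76 ± 0.44, adjusted p = 0.12, or 0.0215 with the block) did not pass without the block. In that fit the cell cycle list had 21 tested members, all 21 below 0, and 17 fell when adjusted over the list alone. TIMP3, a metalloprotease inhibitor, differed by 2.00 ± 0.36 (adjusted p = 0.0537, or 0.0231 with the replicate block), and FGF18 by 2.08 ± 0.37 (adjusted p = 0.0537, or 0.0316 with the block).

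Of 11 tested tubulin genes, a family not tested as a list, 6 fell in ACC and 5 did not pass. Those that fell were TUBB3, TUBA1C, TUBA4A, TUBA1A, TUBB and TUBA1B, with differences of -1.07 to -1.84. On the signals as deposited and after median centring, 1 and 6 of the family fell past the threshold. The 6 named stayed below 0 in both, which differences of that size made likely beforehand. The others were TUBA3C (-1.32, adjusted p = 0.057), TUBA4B (-0.78), TUBB4B (-0.36), TUBB6 (0.09) and TUBB2A (0.07). Tubulin transcripts are close paralogs, so signals of single members are uncertain. Probes with a signal on all 3 arrays of a group and none of the other numbered 151 in ACC and 168 in NCC. Their total of 319 was reached by 5 of the 10 splits of the arrays, with 486 the highest among the other splits. One such probe was that of S100P, a calcium-binding protein, with deposited signals of 81.34, 14.15 and 47.78 in ACC 1 to 3 and blanks in NCC.

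The 6 arrays can be split into 3 and 3 in 10 ways, and 1 of the 10, the real grouping, gave 120 genes, while the highest of the others gave 0. With 10 splits the share cannot fall below 0.1, which is too few to test chance. The real grouping passed 10 lists and the highest other split 5. Among the 4 splits that part all 3 pairs, the real one gave 290 genes with the replicate block and the highest other 0. As there are only 4 such splits, this comparison cannot test chance either.

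The array titled NCC 3 carries a treatment text worded as ACC, so a mislabelled array was tested. Over the 37 genes called without it, its median position was 0.0434 between the NCC mean (0) and the ACC mean (1), with an upper quartile of 0.142 and 2 of the 37 genes nearer ACC. This argues against an ACC array under an NCC title, and a slip in the treatment text is a candidate explanation that was not tested. ACC 2 lay at 0.63 over 134 genes, with 52 nearer NCC, while ACC 1 and ACC 3 lay at 1.02 and 0.97.

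The cell cycle list was lower in ACC, with a median of -1.17 over 10 genes, a call lost at an adjusted p = 0.160 with an estimated correlation. A bias with signal level would give similar medians in lists of matched mean signal, but the list was at percentile 0 of 10000 matched lists, whose lowest median was -0.56. The dimmer arrays numbered 1 did not carry it alone, since 10 of 10 members were lower in ACC in both other pairs, with pair medians of -1.22, -0.98 and -1.60. On the signals as deposited, the list's own median was -1.08 and that of all genes 0.087. These values argue against a factor shared by all genes of an array as the whole cause. Relative to all genes the list lay at -1.17 or lower under 3 scalings, but such a factor cancels there. That measure therefore could not test it, and any scaling before deposit is not known. The waveform itself stays open, and no biological explanation was tested.

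The NRF2 list was higher in ACC, a call lost at an adjusted p = 0.110 with an estimated correlation, and includes AKR1C1, whose probe could take signal from AKR1C paralogs. Without AKR1C1, the 8 remaining members had a median of 0.88 and camera gave p = 2.56e-07 (p = 0.0204 with an estimated correlation, not adjusted over lists). Since all 9 members were above 0, the 8 were bound to be so, which made a small p likely beforehand. The values of the other members, rather than this test, argue against shared AKR1C signal as the whole cause. Whether AKR1C1 and AKR1C4 themselves both rose stays open. NQO1 and HMOX1 are also shear-induced genes, and a shared response to flow or to oxidative stress was not separated here.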
